A study of Mus musculus with 12 samples.

How the data were processed

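RNA was sequenced from 12 samples of BMEL (bipotential mouse embryonic liver) cells, a line of hepatic progenitors that can give rise to hepatocytes and cholangiocytes. The line came from a mouse carrying floxed Cdk8 alleles and, per the labels' protocols, was grown on collagen with serum, insulin, IGF2 and EGF and collected in exponential growth. The 4 groups of 3 samples were untransformed wild-type cells, wild-type cells transformed by H-Ras with the G12V change (called RasG12V below), and RasG12V cells with Cdk8 or with Cdk19 knocked out. The labels do not say that the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

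The deposited values are gene counts, 1 table per library, with reads per Ensembl gene in unstranded and strand-specific columns. The authors ran FastQC and aligned reads with STAR 2.6.0a to GRCm38.p6, per the submitters' processing notes; the annotation release was not given in the sources used here. Per the labels, the RNA was depleted of ribosomal RNA, while the library kit named in the labels is a TruSeq RNA kit. In each of the 12 libraries the reverse-strand column held 24.7 to 28.9 times the reads of the forward-strand column, and the reverse-strand counts (column 4) were used under a rule that asked for a ratio of at least 4 in every library. Reads without a gene were left out of library sizes: 2.10% to 3.34% of reads were unmapped, 23.0% to 26.3% mapped to several places, 4.31% to 5.85% fell outside genes and 0.963% to 1.04% were ambiguous. The remaining 65.2% to 67.0% gave 24823560 to 36879661 gene counts per library, and 3 counts, the floor used for a count of 0, correspond to between 0.0813 and 0.121 CPM in 1 library. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Reads that map to several places were not counted, so members of families with similar sequences, such as the Cyp2c, Ugt2b, Gstm and H2 genes, are uncertain. Of 54146 gene identifiers, 54079 were matched to GENCODE M21 for symbols, biotypes and GRCm38 coordinates and 67 were not.

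Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, glmQLFit with robust estimation and glmQLFTest, with Benjamini-Hochberg adjustment over all 14283 genes tested and a threshold of 0.05. All 12 libraries entered a single fit without a block, so the groups shared an estimate of the spread, and levels are TMM-scaled CPM, given as mean ± SD over 3 libraries unless stated. Log2 fold changes are given with an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, not an error estimated by the model. A fold against a group with 1 to 3 counts is given as a ratio of CPM with its 95% counting interval. Comparisons were RasG12V against untransformed, each knockout against RasG12V, and the Cdk8 knockout against the Cdk19 knockout. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison. Beside it stand camera with an estimated correlation and fry, whose directional test asks whether the members of a list move one way on balance and does not compare them with other genes. Figures were drawn with matplotlib 3.10.9.

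Before the data were examined, the groups, tests, alternatives, 33 gene lists and the rule for named genes were fixed. The 28 pathway lists were ERK output, immediate early genes, EGFR ligands, cytokines and chemokines, matrix proteases, epithelial junction and identity, mesenchymal and EMT, hepatocyte, cholangiocyte and progenitor, S phase and E2F, G2 and mitosis, CDK inhibitors, p53 targets, MYC and nucleolar targets, interferon response, antigen presentation, NF-kB targets, TGF-beta and SMAD, Wnt and beta-catenin, Notch, YAP and TEAD, cholesterol and lipid synthesis, glycolysis and hypoxia, ATF4 and unfolded protein, IGF axis, Mediator kinase module, Mediator core, and Ras family and effectors. The other 5 held markers of stellate cells and fibroblasts, macrophages and leukocytes, erythroid, endothelial and mesothelial cells. Of their 595 entries, 132 were not tested because of low counts. The rule named Cdk8, Cdk19 and Hras. In each comparison it also named the 7 largest rises and falls among protein-coding genes past the threshold with a mean of at least 5 CPM in the higher group, no overlap between libraries and a symbol other than a clone or model number. It further named up to 4 members of each list described, by adjusted p, and the 5 leading genes that changed the same way, and opposite ways, in both knockouts. Some genes that meet this rule are not reported here.

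Each comparison was repeated with RLE size factors, upper quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the unstranded count column, a replicate block by the number in the titles or in the sample descriptions, and each library left out in turn. It was also repeated with only the 2 groups compared, a test against a fold of 1.5, a threshold of 0.01, and without mitochondrial, ribosomal RNA and histone genes. After the data had been seen, 2 settings were added: a fit without replicate 3 of the untransformed and of the RasG12V groups, and limma-voom with library quality weights. The number of lists called between the knockouts was counted under the other settings only then. The fit without those 2 libraries tested 14493 genes and had a common biological coefficient of variation of 6.69%, against 13.9% with all 12.

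The procedure was tested on simulated data, with real library sizes and dispersions and a mean per gene taken over all libraries. In these data 200 genes were changed, and the other genes of the S phase and E2F list were raised 1.5-fold. No library was displaced as in the real data, so the shares recovered hold for that setting only. With all 12 libraries and 14283 genes, edgeR recovered 47.8% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold for RasG12V against untransformed. For the Cdk8 knockout against RasG12V the shares were 43.3%, 82.1% and 97.0%, for the Cdk19 knockout 40.3%, 80.6% and 97.0%, and between the knockouts 49.3%, 89.6% and 100%. Of the unchanged genes, edgeR called 6, 5, 9 and 9 in these comparisons, in the same order, and DESeq2 called 24, 32, 33 and 28. In the real data DESeq2 was run without the filter on low counts, unlike in the simulated data. Because both knockouts were compared with the same RasG12V libraries, 20 sets of counts with unchanged knockouts were simulated for each fit. Every library was redrawn there, and both simulated knockouts were again compared with the same RasG12V libraries.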

Results

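Gene expression was measured by RNA sequencing in 12 samples of BMEL cells, 3 from each of 4 groups: untransformed, RasG12V, Cdk8 knockout with RasG12V and Cdk19 knockout with RasG12V. Cdk8 and Cdk19 are paralogous kinases that associate with cyclin C and Med12 in the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. The series asks how transformation by mutant H-Ras changes the transcriptome of hepatic progenitors, and how depletion of either kinase changes it in transformed cells. Libraries held between 24823560 and 36879661 gene counts.

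The first principal component of log2 CPM held 60.2% of the variance and separated the untransformed libraries (scores -77.5, -74.0 and -58.7) from the transformed ones. RasG12V replicate 3 stood apart from the other RasG12V libraries: its first score was 4.80, against 28 and 28.4, and it lay at -53.2 on the second component, which held 12%. The mean chi-square per gene was 4.79 between RasG12V replicates 1 and 2, but 96.9 and 89.2 between replicate 3 and these. Among the untransformed libraries it was 8.42 for replicates 1 and 2, but 58.6 and 59.5 for replicate 3 with them, while pairs within the knockout groups lay between 10.1 and 20.6. No pair of replicates agreed within sampling noise. RasG12V replicate 3 also had the highest mitochondrial share, 1.92% of gene counts against 1.18% to 1.54% in the other 11 libraries, and the highest ribosomal RNA share, 0.134%.

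**Figure D1:**
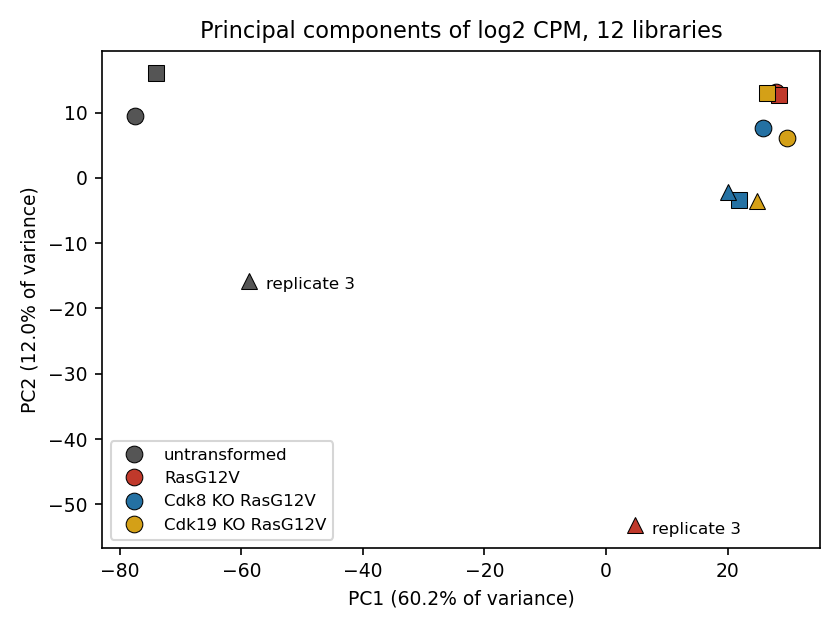
Principal component scores of log2 CPM for the 12 libraries, with the first component on the x axis (60.2% of the variance) and the second on the y axis (12%). Colours mark the groups and shapes the replicates; RasG12V replicate 3 lies at -53.2 on the second component, away from both other RasG12V libraries.

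The targeted genes were measured first. Cdk8 (chromosome 5, 146231230 to 146302874, plus strand, GRCm38) stood at 46.3 ± 2.96 CPM in untransformed cells, 54.5 ± 3.13 in RasG12V, 42.8 ± 1.30 in the Cdk8 knockout and 55.0 ± 2.21 in the Cdk19 knockout (SD, n = 3). Its log2 fold change in the Cdk8 knockout was -0.35 (SE 0.08, adjusted p = 0.415). Without the 2 libraries that stood apart Cdk8 fell there by 0.39 on the log2 scale (SE 0.07, adjusted p = 0.00659). Cdk19 (chromosome 10, 40339564 to 40483818, plus strand) stood at 87.8 ± 4.16, 75.2 ± 16.0, 63.9 ± 5.58 and 49.8 ± 4.22 CPM in the same order. Its log2 fold change in the Cdk19 knockout was -0.60 (SE 0.13, adjusted p = 0.243). Without those 2 libraries it fell there by 0.40 (SE 0.08, adjusted p = 0.0136). In RasG12V replicate 3 Cdk19 was at 93.6 CPM, against 64.7 and 67.2 CPM in replicates 1 and 2. With RasG12V against untransformed its log2 fold change was -0.22 (SE 0.13, adjusted p = 0.250), and -0.40 (SE 0.09, adjusted p = 0.00133) without the 2 libraries. Gene-level counts take reads from every exon, so they do not test the deleted part of either gene and do not check the knockout labels. Hras (chromosome 7, 141189105 to 141194005, minus strand), to which reads of the introduced H-RasG12V may map, rose from 50.0 ± 8.57 to 453 ± 123 CPM, or 9.07-fold, with RasG12V (log2 fold change 3.18, SE 0.19, adjusted p = 4.0e-07). It stood at 451 ± 6.07 CPM in the Cdk8 knockout and 422 ± 18.7 CPM in the Cdk19 knockout. Without the 2 libraries that stood apart, its log2 fold change against RasG12V was -0.21 in the Cdk8 knockout (SE 0.06, adjusted p = 0.0845). In the Cdk19 knockout it was -0.30 (SE 0.06, adjusted p = 0.0133). In RasG12V replicate 3 Hras was at 313 CPM, against 510 and 537 CPM in replicates 1 and 2.

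**Figure D2:**
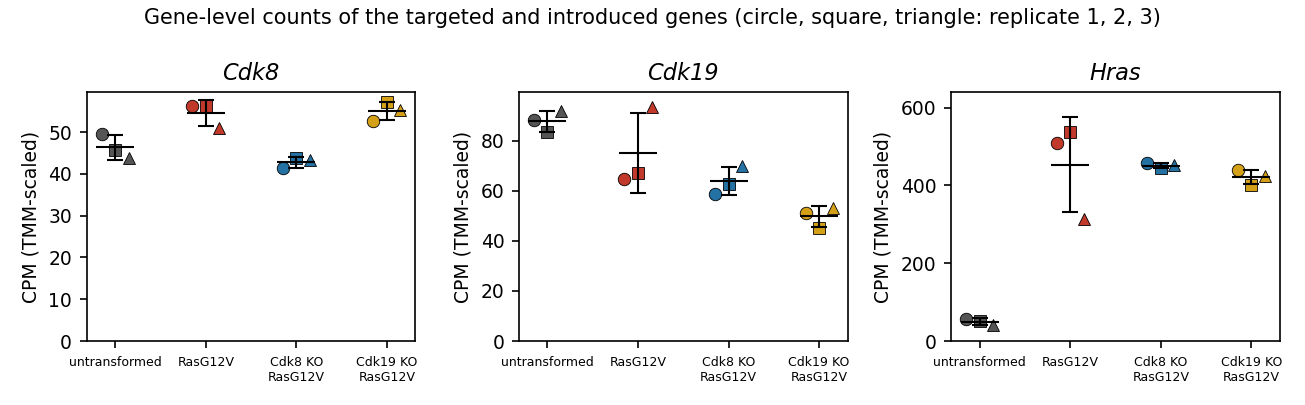
TMM-scaled CPM (y axis) of Cdk8, Cdk19 and Hras in each library of the 4 groups (x axis), with mean and SD. Hras lies at 50.0 CPM on average in untransformed cells and at 422 CPM or more in the transformed groups, while Cdk8 and Cdk19 keep reads in their own knockouts, at 42.8 and 49.8 CPM.

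Mmp10, a stromelysin that degrades extracellular matrix, rose 118-fold with RasG12V, from 0.961 ± 0.243 to 114 ± 42.6 CPM (log2 fold change 6.88, SE 0.38, adjusted p = 2.7e-07). Stc1, a secreted glycoprotein hormone, rose 77.2-fold to 61.3 ± 24.1 CPM, the semaphorin receptor Plxna4 rose 51.1-fold to 10.6 ± 1.19 CPM, and Nlrc5, a transactivator of MHC class I genes, rose 33.9-fold to 7.71 ± 1.51 CPM. Against the 2 counts found over the untransformed group, Lilr4b, a leukocyte immunoglobulin-like receptor, was 793-fold higher (95% counting interval 220 to 6548), and the vesicle protein gene Synpr was 261-fold higher (72.3 to 2156). The secretogranin gene Scg2 was 227-fold higher (77.6 to 1099) than the 3 counts found there. Ttr, the thyroxine carrier made by hepatocytes, fell 120-fold from 32.4 ± 20.2 to 0.242 ± 0.286 CPM (adjusted p = 2.2e-05), and Lbp, which binds lipopolysaccharide, fell 99.9-fold from 16.6 ± 6.16 to 0.148 ± 0.159 CPM. The gastrokine Gkn2 fell 148-fold from 95.9 ± 79.1 CPM, the cytochrome P450 gene Cyp2c65 fell 117-fold from 72.8 ± 53.7 CPM, with reads that may be shared among Cyp2c genes, and Clca1 fell 82.9-fold from 61.1 ± 48.3 CPM. Tff3, a trefoil peptide of mucus, was 242-fold lower (82.8 to 1173) and Pdzk1ip1 was 221-fold lower (75.5 to 1070), each against 3 counts over the RasG12V group. The wide spread of the untransformed group in these genes came with its replicate 3, in which Gkn2 was at 4.68 CPM against 144 and 139 CPM in replicates 1 and 2. Without replicate 3 of both groups the falls were 548-fold for Ttr, 561-fold for Gkn2, 224-fold for Cyp2c65 and 164-fold for Clca1, and the rise of Stc1 was 44.9-fold. Lbp was then 355-fold lower (122 to 1723, against 3 counts), Pdzk1ip1 560-fold lower (101 to 22121, against 1 count) and Lilr4b at least 257-fold higher, against 0 counts.

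In all, 1701 genes rose and 1639 fell with RasG12V, 667 and 636 of them by at least 1 on the log2 scale. The libraries of the 2 groups did not overlap for 4619 genes, 32.3% of those tested, where chance gives 10%. Without replicate 3 of both groups, 2754 genes rose and 3045 fell, and 3167 of the 3340 genes called with all libraries were called again. The count was 4808 without RasG12V replicate 3 alone, and 1574 when only these 2 groups entered the fit.

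Of 17 tested genes of the ERK output list, which record signalling through the ERK kinases, 12 rose and 1 fell with RasG12V, over all genes and adjusted over the list alone (camera adjusted p = 6.0e-07; adjusted p = 0.0519 with an estimated correlation). The phosphatase gene Dusp5 rose by 1.45 (SE 0.13, 37.7 to 103 CPM), the transcription factor Etv5 by 0.94 (SE 0.10), and the feedback inhibitors Spred3 and Spry2 by 1.58 (SE 0.17) and 1.15 (SE 0.14). Of 16 immediate early genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.394 with an estimated correlation). The leading genes were Fosb (3.71, SE 0.31), Nr4a1 (0.93, SE 0.12), Egr3 (2.38, SE 0.46, and 1.26 without both replicates 3) and Egr1 (1.44, SE 0.36). This list did not pass without untransformed replicate 3 (adjusted p = 0.144) or without both replicates 3 (0.172). In untransformed replicate 3 its members had a median log2 ratio of -0.21 against replicates 1 and 2, and Egr1 did not pass without untransformed replicate 1 or 2 (adjusted p = 0.0539 and 0.0565). Glycolysis and hypoxia genes rose in 11 and fell in 2 of 21 cases (12 and 2 adjusted over the list alone; camera adjusted p = 4.3e-05; adjusted p = 0.0577 with an estimated correlation). Among them the glycolytic enzymes Pfkl, Hk1 and Pfkp rose by 0.75 (SE 0.07), 0.77 (SE 0.07) and 1.43 (SE 0.16). The pyruvate dehydrogenase kinase gene Pdk1 rose by 1.14 (SE 0.12).

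Matrix protease genes went both ways: 5 of 14 rose and 3 fell, also adjusted over the list alone, with a camera adjusted p = 0.000628 for a rise (adjusted p = 0.0519 with an estimated correlation; 0.0866 without untransformed replicate 3 and 0.0586 without both replicates 3). Beside Mmp10, the cathepsin gene Ctsl rose by 1.62 (SE 0.11, 754 to 2325 CPM), the plasminogen activator Plat by 1.41 (SE 0.12) and the collagenase Mmp13 by 4.89 (SE 0.48, 17.9 to 531 CPM; 3.98 without both replicates 3). Antigen presentation genes rose in 4 of 10 cases, also adjusted over the list alone (camera adjusted p = 0.000675; adjusted p = 0.291 with an estimated correlation; 0.142 without RasG12V replicate 3). This list passed without both replicates 3 (adjusted p = 0.0321; adjusted p = 0.603 with an estimated correlation), with 5 rises and 2 falls. The 4 genes were Nlrc5, B2m (0.76, SE 0.10), H2-D1 (0.89, SE 0.12) and H2-K1 (1.03, SE 0.21), where reads may be shared among H2 genes. The members of this list had a median log2 ratio of 0.54 in untransformed replicate 3 against replicates 1 and 2, and of 0.40 in RasG12V replicate 3 against its replicates.

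In the epithelial junction and identity list 9 of 12 fell and 1 rose with RasG12V (10 and 1 adjusted over the list alone; camera adjusted p = 0.000628; adjusted p = 0.192 with an estimated correlation). The desmosomal gene Dsp fell by 0.60 (SE 0.08), the polarity gene Crb3 by 1.60 (SE 0.24), the tight junction gene Marveld2 by 1.26 (SE 0.22) and the keratin gene Krt8 by 0.61 (SE 0.11). In the hepatocyte list 6 of 16 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0049; adjusted p = 0.396 with an estimated correlation). Ttr fell by 6.91 (SE 0.70), Alb had 3.05 ± 1.21 CPM in untransformed cells and 0.0201 ± 0.0348 CPM in RasG12V, and the pioneer factor Foxa1 rose by 1.22 (SE 0.11). Without the 2 libraries 13 of these 16 genes fell. The hepatocyte list had a median log2 ratio of -0.29 in untransformed replicate 3, and of 0.95 in RasG12V replicate 3, against the other replicates of the group. In the cholangiocyte and progenitor list 7 of 16 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.00347; adjusted p = 0.291 with an estimated correlation). The RNA-binding protein gene Bicc1 fell by 3.56 (SE 0.175, 820 to 69.4 CPM), Krt7 by 1.13 (SE 0.12) and the chloride channel Cftr by 2.35 (SE 0.32). The median log2 ratio of this list was -0.23 in untransformed replicate 3 and 0.28 in RasG12V replicate 3.

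Targets of YAP and TEAD, the effectors of Hippo signalling, fell in 9 of 16 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.00023; adjusted p = 0.291 with an estimated correlation). Among them were Nuak2 (-1.57, SE 0.11), Ajuba (-0.87, SE 0.12), Amotl2 (-1.17, SE 0.19) and Gadd45b (-1.39, SE 0.26). Without the 2 libraries that stood apart 10 fell and 3 rose in edgeR. TGF-beta and SMAD genes fell in 9 of 17 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.000738; adjusted p = 0.142 with an estimated correlation). The integrin gene Itgb6 fell by 4.38 (SE 0.37), Id2 by 0.93 (SE 0.10), Tgfb3 by 2.80 (SE 0.42) and Pmepa1 by 0.97 (SE 0.18). In RasG12V replicate 3 the median log2 ratios of these lists against replicates 1 and 2 were -0.44 and -0.54. Of 29 S phase and E2F genes 8 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.000781; adjusted p = 0.762 with an estimated correlation). Those with the smallest adjusted p were the licensing factor Cdt1 (-0.61, SE 0.13), Lig1 (-0.70, SE 0.17), Pcna (-0.54, SE 0.13) and Mcm6 (-0.68, SE 0.17). Their median log2 ratio was -0.97 in RasG12V replicate 3 and -0.31 in untransformed replicate 3, and the list did not pass without RasG12V replicate 3 (adjusted p = 0.147). Without both replicates 3 it was again lower (adjusted p = 0.0137; adjusted p = 0.740 with an estimated correlation), and 19 of the 29 genes fell and 0 rose. Pcna did not pass without untransformed replicate 1 (adjusted p = 0.0520).

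**Figure D3:**
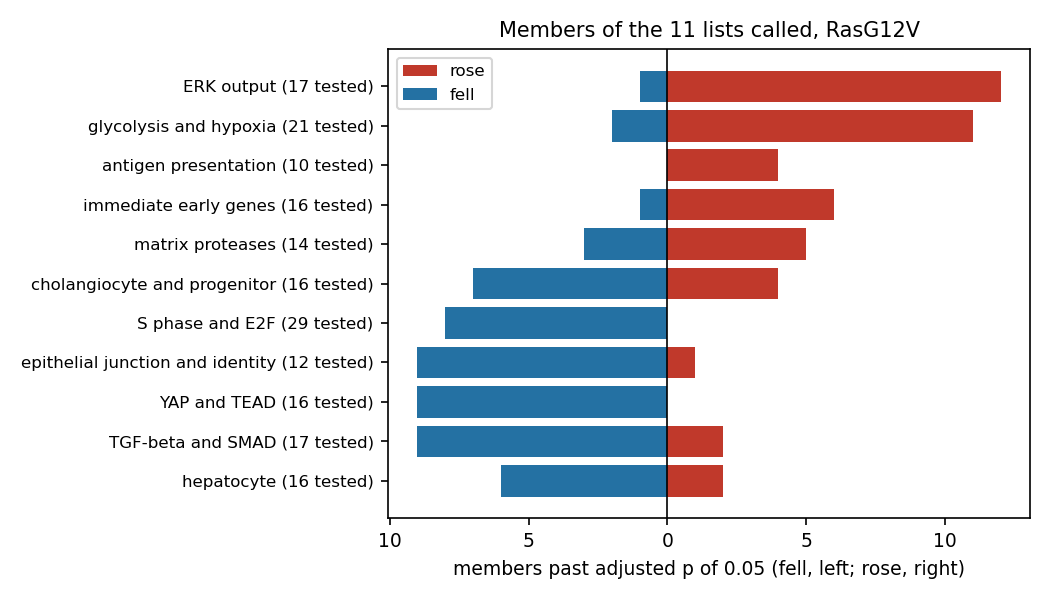
Members of the 11 gene lists called by camera that rose (right) or fell (left) past an adjusted p of 0.05 in RasG12V against untransformed cells, as counts on the x axis, with the number tested beside each list. Lists are ordered by median log2 fold change, from ERK output (12 rises and 1 fall) to hepatocyte (2 rises and 6 falls). The YAP and TEAD list has 9 falls and 0 rises.

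The other lists did not pass by camera with RasG12V. Wnt and beta-catenin genes rose in 5 and fell in 2 of 9 cases (adjusted p = 0.0555), with Wnt5a up by 3.08 (SE 0.22) and Apcdd1 by 1.68 (SE 0.13). NF-kB targets rose in 1 and fell in 5 of 12 cases (adjusted p = 0.0555; 9 falls adjusted over the list alone), and mesenchymal and EMT genes rose in 5 and fell in 2 of 12 (adjusted p = 0.131), with Zeb2 up by 1.34 (SE 0.11) and Sparc down by 1.09 on the log2 scale (-1.09, SE 0.14). In the IGF axis 2 rose and 4 fell of 14 (adjusted p = 0.234). The binding protein genes Igfbp4 and Igfbp3 rose by 1.43 (SE 0.08) and 0.94 (SE 0.08), while Igfbp7 and the receptor substrate gene Irs2 fell by 3.29 (SE 0.205) and 2.08 (SE 0.17). Cholesterol and lipid synthesis genes rose in 5 and fell in 1 of 25 cases (adjusted p = 0.0909), and Ras family and effectors in 5 and 2 of 19 (0.211). For cytokines and chemokines the counts were 3 and 2 of 7 (0.792), with Ccl20 down at a log2 fold change of -3.56 (SE 0.27), for EGFR ligands 1 and 1 of 7 (0.548), for CDK inhibitors 3 and 1 of 7 (0.579) and for p53 targets 7 and 5 of 28 (0.662). Interferon response genes rose in 0 and fell in 5 of 17 cases (0.517), Notch genes in 2 and 4 of 10 (0.597), G2 and mitosis genes in 0 and 1 of 25 (0.507), MYC and nucleolar targets in 0 and 0 of 20 (0.507) and ATF4 and unfolded protein genes in 1 and 2 of 18 (0.579). In the Mediator kinase module 3 rose and 1 fell of 7 (0.517). Ccnc, Med12 and Cdk8 rose by 0.39 (SE 0.09), 0.29 (SE 0.07) and 0.23 (SE 0.08), and Med12l fell by 0.76 (SE 0.24). Med12 did not pass without untransformed replicate 1 (adjusted p = 0.0594). Med12l passed only without RasG12V replicate 2 or without Cdk19 knockout replicate 2 or 3 when 1 library was left out, and did not pass with the unstranded column (0.202) or without both replicates 3 (0.0846). Cdk8 did not pass without untransformed replicate 2 or 3, RasG12V replicate 1 or 2, or replicate 3 of either knockout (adjusted p = 0.132, 0.0943, 0.107, 0.106, 0.0654 and 0.0644). In the Mediator core 1 rose and 1 fell of 26 (0.909). Markers of macrophages and leukocytes rose in 1 and fell in 0 of 4 cases (0.579), erythroid in 0 and 0 of 2 (0.645), endothelial in 1 and 0 of 4 (0.597) and mesothelial in 1 and 2 of 5 (0.507). Of the stellate cell and fibroblast markers Pdgfra alone was tested, and it rose by 1.59 (SE 0.26). The mean and the test differed in sign for p53 targets and for ATF4 and unfolded protein genes.

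Some of these lists depended on the libraries used. Without replicate 3 of both groups, 5799 of all 14493 genes tested passed, against 3340 of 14283 with all 12 libraries. A larger number of list members that passed is therefore not by itself a result about a list. Without replicate 3 of both groups, ATF4 and unfolded protein genes were lower with RasG12V (camera adjusted p = 0.0247; adjusted p = 0.337 with an estimated correlation), with 1 rise and 12 falls of 18. The rises and falls were then 9 and 0 of 20 for MYC and nucleolar targets (adjusted p = 0.144), 6 and 2 of 25 for G2 and mitosis (0.454), 9 and 2 of 25 for cholesterol and lipid synthesis (0.144), 7 and 5 of 19 for Ras family and effectors (0.130), 3 and 5 of 17 for interferon response (0.454), 5 and 1 of 7 for the Mediator kinase module (0.503) and 3 and 1 of 26 for the Mediator core (0.879). For mesothelial markers they were 3 and 2 of 6 (0.879), where the median log2 fold change turned from -0.13 to 1.39. With 1 library left out, MYC and nucleolar targets were higher without RasG12V replicate 3 (0.00578), and NF-kB targets lower without untransformed replicate 1 or 2 (0.0365 and 0.0350). Wnt and beta-catenin genes were higher without untransformed replicate 1, RasG12V replicate 1 or 2, or Cdk19 knockout replicate 2 (0.0365, 0.0234, 0.0348 and 0.0350). Cholesterol and lipid synthesis genes were higher without untransformed replicate 3 or RasG12V replicate 1 or 2 (0.0147, 0.0144 and 0.0237). With an estimated correlation each of these calls with 1 library left out had an adjusted p of 0.222 or more.

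In the Cdk8 knockout, 0 genes passed against RasG12V in edgeR with all 12 libraries: 871 genes had an unadjusted p under 0.05, where 714 would by chance, and the smallest adjusted p was 0.212. Limma-voom called 0 and DESeq2 called 30, where DESeq2 called 32 unchanged genes in the simulated data for this comparison. With RasG12V replicate 3 alone left out, 3 genes passed in edgeR. Untransformed replicate 3 is in neither group compared, and entered through the shared estimate of the spread, the scaling and the filter. After the 2 libraries that stood apart had been left out, a choice made once the data had been seen, 171 genes rose and 60 fell. In that fit, with 3 knockout and 2 RasG12V libraries, Nat8l, which makes N-acetylaspartate, rose from 2.67 ± 0.224 to 7.97 ± 1.52 CPM (log2 fold change 1.57, SE 0.20, adjusted p = 0.000342). Il1rn, the antagonist of the interleukin-1 receptor, rose from 3.55 ± 0.155 to 10.4 ± 1.19 CPM (1.55, SE 0.20). The uroplakin gene Upk1b rose by 1.47 (SE 0.19), the galectin gene Lgals4 by 1.10 (SE 0.11), Mst1r, the receptor of macrophage-stimulating protein, by 1.03 (SE 0.18), Ugt1a7c by 1.01 (SE 0.11) and Tmem151a by 0.99 (SE 0.19). The direction for Lgals4 turned with the libraries used: it was -0.62 (adjusted p = 0.904) with all 12, where RasG12V replicate 3 stood at 54.2 CPM. The transcription factor Klf2 fell by 1.21 (SE 0.18, adjusted p = 0.00263), the hyaluronan synthase Has3 by 0.50 (SE 0.10), Aldh1a1, which makes retinoic acid, by 0.44 (SE 0.06), Cpeb4 by 0.43 (SE 0.08), Phip by 0.42 (SE 0.08) and the caspase-8 regulator Cflar by 0.41 (SE 0.07). The libraries did not overlap for 1791 genes, 12.5% of those tested with all 12, where chance gives 10%.

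By camera, the S phase and E2F list (29 tested, median log2 fold change 0.27, adjusted p = 8.5e-10) and the G2 and mitosis list (25 tested, median 0.23, adjusted p = 2.9e-06) were higher in the Cdk8 knockout than in RasG12V. Each had an adjusted p = 0.741 with an estimated correlation, and 0 of their members passed in edgeR, over all genes or adjusted over the list alone. Rfc4 and Pcna had log2 fold changes of 0.22 (SE 0.09) and 0.28 (SE 0.13) and Ccnb2 of 0.29 (SE 0.11). Neither list passed without RasG12V replicate 3 (adjusted p = 0.882 and 0.409, the latter for a fall), a library in which their members were lower, with median log2 ratios of -0.97 and -0.81 against replicates 1 and 2. Camera called 6 lists without RasG12V replicate 1 or 2, and 5 without RasG12V replicate 3 or Cdk8 knockout replicate 2. Without the 2 libraries it called 4 other lists. Cholesterol and lipid synthesis was higher (4 of 25 rose, 12 adjusted over the list alone; adjusted p = 1.2e-07; adjusted p = 0.44 with an estimated correlation). The desaturase gene Scd1 rose by 0.87 (SE 0.12, but -0.02 when RasG12V replicate 1 alone was left out) and Mvd by 0.47 (SE 0.10). Fdft1 rose by 0.43 (SE 0.11, but -0.09 when RasG12V replicate 1 alone was left out). Hmgcs1 rose by 0.31 (SE 0.08) and was at -0.04 with all 12 libraries. The hepatocyte list was higher (2 of 16 rose, 6 adjusted over the list alone; 0.0124; 0.44 with an estimated correlation), with Afp up by 0.43 (SE 0.09) and Rbp4 by 0.49 (SE 0.11), against -0.25 with all 12. Glycolysis and hypoxia was higher (1 of 21 rose, 3 adjusted over the list alone; 0.0284; 0.522 with an estimated correlation). MYC and nucleolar targets were lower (0 of 20 passed, 3 falls adjusted over the list alone; 0.000475; 0.471 with an estimated correlation). With all 12 libraries the hepatocyte and MYC lists had the opposite direction and did not pass (adjusted p = 0.570 and 0.436). The hepatocyte list was lower without RasG12V replicate 2 (0.0410) and higher without replicate 3 (0.0136), and MYC and nucleolar targets were higher without RasG12V replicate 1 or 2 (0.0108 and 0.0257) and lower without replicate 3 (0.00631), each at an adjusted p of 0.399 or more with an estimated correlation. The signs of median, mean and test were not all alike with all 12 for the lists of cholangiocyte and progenitor, ERK output, cytokines and chemokines, interferon response, EGFR ligands, NF-kB targets and erythroid genes.

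In the Cdk19 knockout, 2 genes passed against RasG12V with all 12 libraries, both named after their values were seen. Rgs5, a regulator of G protein signalling, fell 6.28-fold from 2.67 ± 0.608 to 0.422 ± 0.189 CPM (log2 fold change -2.65, SE 0.33, adjusted p = 0.0388). Gm38020, an unclassified transcript on the X chromosome, rose 8.12-fold from 0.385 ± 0.300 to 3.12 ± 0.353 CPM (adjusted p = 0.0388). Gm38020 did not pass with a block by title number (adjusted p = 0.0671). DESeq2 called 66 genes. It called 33 unchanged genes in the simulated data, which again held changed genes and a filter and do not give the number of false calls here. In edgeR 1089 genes had an unadjusted p under 0.05. The count of 2 was 0 without untransformed replicate 1 or 2, any 1 Cdk8 knockout library, or Cdk19 knockout replicate 1 or 2. It was 1 without RasG12V replicate 1 or Cdk19 knockout replicate 3, 10 without RasG12V replicate 3 and 21 without untransformed replicate 3. After both replicates 3 had been left out, 161 genes rose and 130 fell, with Rgs5 and Gm38020 among them. In that fit, again with 3 knockout and 2 RasG12V libraries, Crisp1, which encodes a cysteine-rich secretory protein, fell from 76.5 ± 0.570 to 19.8 ± 1.85 CPM (log2 fold change -1.95, SE 0.08, adjusted p = 8.2e-12). Clu, the secreted chaperone clusterin, fell from 2478 ± 32.0 to 1191 ± 133 CPM (-1.06, SE 0.08). Cyp2c68, with reads that may be shared among Cyp2c genes, fell by 1.78 (SE 0.21), Scg2 by 1.25 (SE 0.22), the cornified envelope gene Ivl by 1.24 (SE 0.16), the matrix gene Tnc by 1.11 (SE 0.17) and Serpinb2, an inhibitor of plasminogen activators, by 1.02 (SE 0.09). Lgals4 rose from 7.01 ± 0.224 to 20.97 ± 1.20 CPM (1.58, SE 0.11), Gstm1, whose reads may be shared with other Gstm genes, by 1.49 (SE 0.20), the kinase gene Sgk2 by 1.13 (SE 0.21), the collagen gene Col8a1 by 0.96 (SE 0.17), Ssbp2 by 0.93 (SE 0.15), Smim6 by 0.92 (SE 0.21) and Gchfr by 0.82 (SE 0.14). With all 12 libraries the direction turned for Lgals4 (-0.13, adjusted p = 0.971; 54.2 CPM in RasG12V replicate 3) and for Smim6 (-0.08). It turned for Gstm1 without RasG12V replicate 1 or 2 alone (-0.14 and -0.12). Hras fell by 0.30 (SE 0.06, adjusted p = 0.0133) without both replicates 3, and its log2 fold change with all libraries was -0.10 (SE 0.17). The libraries did not overlap for 2075 genes, 14.5% of those tested with all 12, where chance gives 10%.

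Camera called 8 lists in the Cdk19 knockout with all 12 libraries, and 0 of their members passed in edgeR over all genes. S phase and E2F (29 tested, median log2 fold change 0.27, adjusted p = 2.2e-09; adjusted p = 0.722 with an estimated correlation), G2 and mitosis (25 tested, 0.00295; 0.766 with an estimated correlation) and MYC and nucleolar targets (20 tested, 0.00417; 0.766) were higher. Lower were the hepatocyte, cholangiocyte and progenitor, and epithelial junction lists (16, 16 and 12 tested; adjusted p = 0.0209 for each; 0.766, 0.707 and 0.707 with an estimated correlation), Wnt and beta-catenin (9 tested, 0.0276; 0.707) and immediate early genes (16 tested, 0.0348; 0.722). Adjusted over the list alone, 2 cholangiocyte and progenitor, 1 epithelial and 2 Wnt genes fell, Sox4 and Onecut2 having log2 fold changes of -0.45 (SE 0.12) and -0.41 (SE 0.11), Dsp of -0.31 (SE 0.08), Rnf43 of -0.51 (SE 0.09) and Wnt5a of -0.85 (SE 0.20). Without RasG12V replicate 3 the count of lists was 2, with S phase and E2F at an adjusted p = 0.576. In that setting G2 and mitosis turned to lower (0.0451, but 0.894 with an estimated correlation). The hepatocyte list turned to higher (median 0.06, adjusted p = 0.672) and MYC and nucleolar targets to lower (median -0.04, adjusted p = 0.623), neither passing. The count was also 2 without Cdk19 knockout replicate 2, and 0 without both replicates 3. Without a filter the epithelial, hepatocyte and Wnt lists did not pass (adjusted p = 0.214, 0.277 and 0.954), and immediate early genes and the epithelial list did not without Cdk19 knockout replicate 1 (0.223 and 0.0559). The cholangiocyte and Wnt lists did not pass without Cdk19 knockout replicate 3 (0.0656 and 0.0928). In RasG12V replicate 3 the median log2 ratios against replicates 1 and 2 were -0.69 for MYC and nucleolar targets, 0.40 for the epithelial list, 0.24 for immediate early genes and 0.16 for Wnt and beta-catenin. Median, mean and test were not all alike in sign for mesenchymal and EMT, glycolysis and hypoxia, IGF axis, Notch, TGF-beta and SMAD, mesothelial and erythroid genes.

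The knockouts were compared directly. Nt5e, the ecto-nucleotidase CD73, was 2.75-fold higher in the Cdk8 knockout, at 23.2 ± 2.86 CPM, than in the Cdk19 knockout, at 8.43 ± 1.35 CPM (log2 fold change 1.46, SE 0.16, adjusted p = 0.00622). The small proline-rich gene Sprr2h was 2.34-fold higher (74.4 ± 6.90 against 31.8 ± 0.633 CPM), the cadherin gene Cdh6 1.99-fold (74.1 ± 9.62 against 37.2 ± 0.838 CPM), the sciellin gene Scel 1.63-fold, Gimd1 1.63-fold, Rnf43, a ubiquitin ligase that dampens Wnt signalling, 1.62-fold and Cfap69 1.56-fold. Cfap69 did not pass with a block by title number (adjusted p = 0.0654). Adgra2, a co-receptor of Wnt7 signalling, was 1.81-fold lower (40.9 ± 2.47 against 74.1 ± 3.49 CPM) and the pyruvate carboxylase gene Pcx 1.48-fold lower (21.1 ± 0.598 against 31.2 ± 1.83 CPM). These were among 11 genes higher and 4 lower in the Cdk8 knockout, with non-overlapping libraries for each. They did not overlap for 2955 genes, 20.7% of those tested, where chance gives 10%. When only these 2 groups entered the fit, 496 genes passed.

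The count of 15 was 73 without untransformed replicate 3, 133 without RasG12V replicate 3 and 771 (521 higher, 250 lower) without both, with all 15 among the 771. These 2 libraries are in neither group compared, and entered through the shared estimate of the spread, the scaling and the filter. Without both, Nt5e kept its log2 fold change of 1.46 while its SE went from 0.16 to 0.11. Adgra2 stayed at -0.86 while its SE went from 0.14 to 0.06. The count was 8, 9 and 10 without RasG12V replicate 1, untransformed replicate 1 and untransformed replicate 2. Without replicate 1, 2 or 3 of the Cdk8 knockout it was 1, 5 and 0, and without those of the Cdk19 knockout 0, 1 and 0. In the fit without both replicates 3, chosen after the data had been seen, Crisp1 was higher in the Cdk8 knockout by 1.88 (SE 0.07), Cyp2c68 by 1.80 (SE 0.19), Nat8l by 1.75 (SE 0.17), Upk1b by 1.62 (SE 0.16), Mst1r by 1.52 (SE 0.16) and the annexin gene Anxa10 by 1.46 (SE 0.08). Col8a1 was lower (log2 fold change -1.51, SE 0.15), as were the proteoglycan gene Acan (-0.89, SE 0.15), Klf2 (-0.87, SE 0.17), Gstm1 (-0.74, SE 0.16), the linker histone gene H1f0 (-0.74, SE 0.06) and Gpr155 (-0.65, SE 0.16). By camera with all 12 libraries 3 lists were higher in the Cdk8 than in the Cdk19 knockout. The count was 7 without RasG12V replicate 3, 5 without Cdk8 knockout replicate 2, 1 without Cdk8 knockout replicate 3 and 5 without both replicates 3. Matrix proteases were higher (0 of 14 passed, 2 adjusted over the list alone; adjusted p = 0.00295; adjusted p = 0.102 with an estimated correlation; fry adjusted p = 0.0367). Mmp10 had a log2 fold change of 1.38 (SE 0.27). Also higher were Wnt and beta-catenin (1 of 9, Rnf43, 2 adjusted over the list alone; 0.00694; 0.285 with an estimated correlation; 0.0565 without Cdk8 knockout replicate 3 and 0.159 without a filter), and cholesterol and lipid synthesis (0 of 25, 0 adjusted over the list alone; 0.0165; 0.767 with an estimated correlation; 0.1005 without Cdk8 knockout replicate 3 and 0.0502 without Cdk19 knockout replicate 2). The immediate early list was higher (0.0379; 4 of 16 genes passed) and MYC and nucleolar targets lower (0.0117; 0 of 20 passed) without both replicates 3, each at an adjusted p = 0.525 with an estimated correlation. Median and test differed in sign for the YAP and TEAD, Mediator kinase module, IGF axis and mesothelial lists, and mean and test for the CDK inhibitors.

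**Figure D4:**
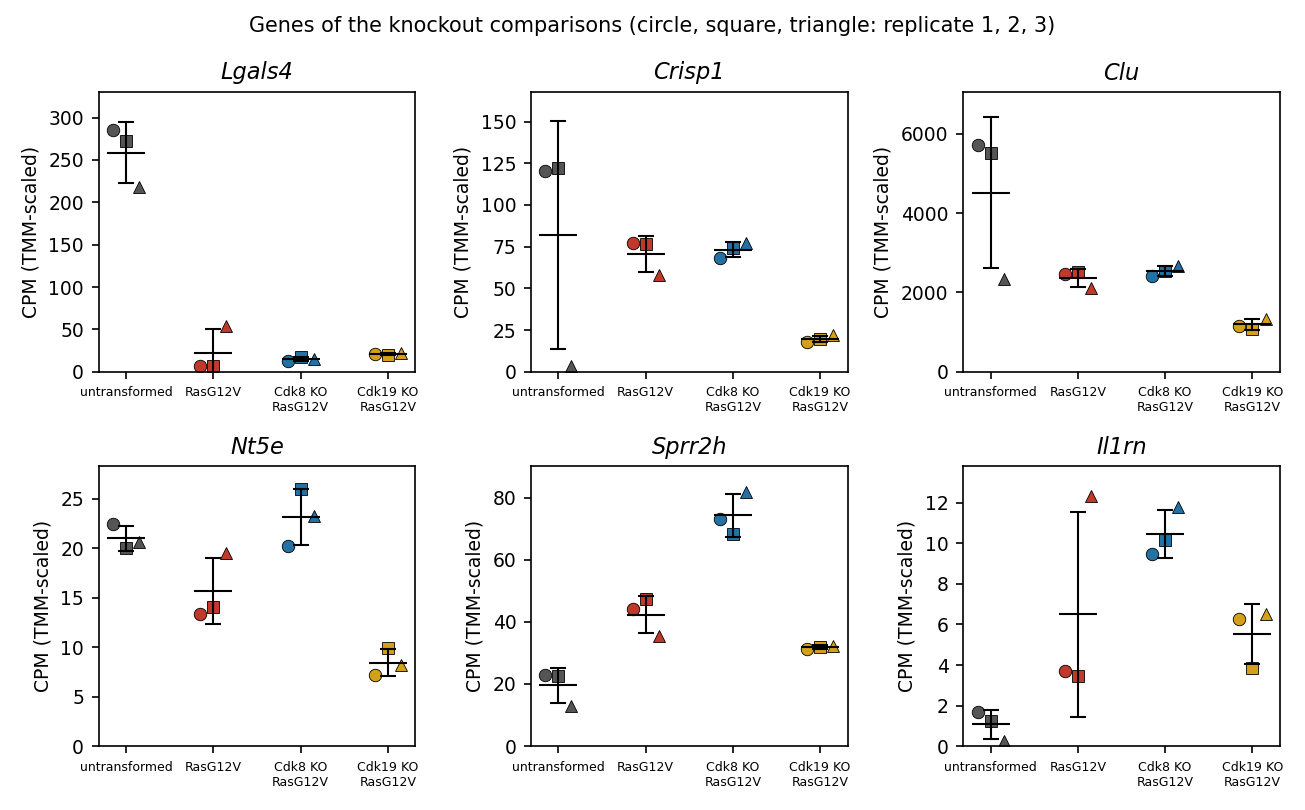
TMM-scaled CPM (y axis) of 6 genes in each library of the 4 groups (x axis), with mean and SD over 3 libraries and a shape for each replicate. Lgals4 lies at 54.2 CPM in RasG12V replicate 3 against 6.89 and 7.24 CPM in replicates 1 and 2, and Crisp1 at 3.19 CPM in untransformed replicate 3 against 120 and 122 CPM.

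Genes shared by the knockouts, and genes moved back towards the untransformed level, were counted last. With all 12 libraries 0 genes passed in both knockouts against RasG12V in edgeR (0 by limma-voom, 5 by DESeq2, and 1 in edgeR without RasG12V replicate 3). The log2 fold changes of the knockouts had a Pearson correlation of 0.54 across genes, which are not independent replicates. Counts simulated with unchanged knockouts gave 0.51 (0.47 to 0.53), with a covariance of 0.0390 (0.0359 to 0.0428) beside 0.0531 observed. The RasG12V libraries were redrawn there as well, with no library displaced from its group. RasG12V replicate 3 still entered the means and dispersions used with all 12 libraries, so its displacement could widen the simulated spread. Without both replicates 3, 32 genes rose and 11 fell in both knockouts, where independent lists would share 1.90 and 0.538 and the simulations gave 0.1 in all, and 9 went opposite ways. The correlation was then 0.63 beside 0.64 (0.61 to 0.68) simulated, and the covariance 0.0880 beside 0.0477 (0.0423 to 0.0540). The RasG12V libraries could not be split into 2 parts of at least 2, so part of the excess may come from the shared libraries. In that fit Lgals4 rose by 1.10 and 1.58 in the Cdk8 and Cdk19 knockouts (-0.62 and -0.13 with all 12 libraries). Scd1 rose by 0.87 and 0.76 (-0.02 and -0.13 when RasG12V replicate 1 alone was left out) and Kbtbd11 by 0.74 and 0.71. The tetraspan gene Emp2 rose by 0.70 and 0.77, and Fgfbp1, which releases fibroblast growth factors, by 0.69 and 0.63. Nt5e rose by 0.76 in the Cdk8 knockout and fell by 0.70 in the Cdk19 knockout, Anxa10 rose by 0.68 and fell by 0.78, the scaffold gene Akap12 rose by 0.74 and fell by 0.66, and Sprr2h rose by 0.71 and fell by 0.52. Adgra2 fell by 0.39 and rose by 0.47.

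Of the 3340 genes that changed with RasG12V, 0 passed in the opposite direction in the Cdk8 knockout with all 12 libraries (15 by DESeq2) and 1, Rgs5, in the Cdk19 knockout (30 by DESeq2). Simulated unchanged groups gave 0.1 for each. The count for the Cdk8 knockout was 3 without RasG12V replicate 3. That for the Cdk19 knockout was 7 without untransformed replicate 3 or RasG12V replicate 3, 2 without RasG12V replicate 2, 1 without Cdk19 knockout replicate 3, and 0 without any other single library. Without both replicates 3, 5799 genes changed with RasG12V. In the Cdk8 knockout 149 of them moved back and 29 further, where independent lists would share 47.3 and 45.1. In the Cdk19 knockout 146 moved back and 76 further, where they would share 58.5 and 57.9. The simulations gave 0.5 moved back for each. In that fit Lgals4, at 280 CPM in untransformed replicates 1 and 2 and 7.01 CPM in RasG12V replicates 1 and 2, stood at 14.9 and 20.97 CPM in the Cdk8 and Cdk19 knockouts. RasG12V replicate 3 was at 54.2 CPM, above both knockouts, and with all 12 libraries the direction turned (log2 fold changes -0.62 and -0.13, neither passing).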

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

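The tests of depth, and of which RasG12V library was left out, were set before their results were seen; the tests of mixture, growth, shared libraries, the S phase list and other splits of the libraries were chosen after the results were seen.

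The direct comparison of the knockouts was marked because the effects of the 2 deletions differed by a test of the difference itself: 15 genes passed between them, among them Nt5e, Sprr2h, Cdh6, Rnf43 and Adgra2. Of the 10 splits of these 6 libraries into groups of 3, 1 (the real one) gave as many, and the highest count in another split was 0, but 10 splits are too few for a share under 0.05. For gene lists 3 of the 10 gave as many as the real 3 (highest other 8). No biological explanation beyond the labelled genotypes was tested, and a difference between clones or cultures of the 2 knockouts was not tested.

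RasG12V replicate 3 stood apart from replicates 1 and 2, and a mixture with cells like untransformed replicates 1 and 2 was argued against: Hras would need a share of 45.0%, while 12 genes abundant there and nearly absent from RasG12V replicates 1 and 2 stood at a median of 1.92% of that level (quartiles 1.03% and 3.08%). A mixture with cells like untransformed replicate 3, left out of that level, cannot be told apart: these genes were at 2.98 to 29.3 CPM in that library, and their median in RasG12V replicate 3 was 12.1% of its level (quartiles 8.01% and 25.3%), with 2 genes over the 43.7% that Hras would need. Sequencing depth was argued against as well, since the chi-square per gene with replicates 1 and 2 was 79.8 or more after thinning to 24823560 counts, against at most 20.6 in the knockout groups. Slower growth of that culture stays open and is in line with the lower S phase list (median log2 ratio -0.974) and G2 and mitosis list (-0.809), in which all 29 and 25 members were lower. No biological explanation from the design was tested, as the labels give the 3 libraries the same state.

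The S phase and E2F list was higher in each knockout than in RasG12V by camera, with 0 of its 29 members passing and an adjusted p = 0.741 and 0.722 with an estimated correlation in the Cdk8 and Cdk19 knockouts. The values were in line with an effect of RasG12V replicate 3 alone, because without that library the camera adjusted p was 0.882 for the Cdk8 knockout and 0.576 for the Cdk19 knockout. An effect of either kinase on the cell cycle genes was therefore not separated from that library.

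Without both replicates 3, more RasG12V genes moved back towards the untransformed level in the knockouts than further away. The covariance of the RasG12V and knockout changes was -0.160 for the Cdk8 knockout and -0.0904 for the Cdk19 knockout, below the -0.0703 and -0.0689 that were the lowest values of simulated unchanged knockouts. Because the RasG12V libraries enter both changes with opposite signs, and a simulated range excludes nothing alone, an effect of the shared libraries cannot be told apart from one of the knockouts. The simulations also redrew the RasG12V libraries, with no library displaced from its group. With all 12 libraries, however, the dispersions used were estimated with replicate 3 among them. Without both replicates 3, Hras had log2 fold changes of -0.21 and -0.30 in the Cdk8 and Cdk19 knockouts. Whether its level moved the other genes was not tested. With all 12 libraries the covariances were -0.0199 and 0.0147, above the simulated ranges of -0.0510 to -0.0252 and -0.0453 to -0.0261; with RasG12V replicate 3 left out alone they were -0.166 and -0.105, with replicate 1 left out -0.0519 and -0.00865, and with replicate 2 left out -0.0577 and -0.0127. The choice of the library left out thus stays open too, since replicate 3 was the RasG12V library nearest to the untransformed ones on the first principal component.

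Other splits of the 6 libraries of a comparison were counted, and 10 splits are too few for a share under 0.05. For RasG12V against untransformed, 1 split gave as many genes as the 3340 of the real one (highest other 18) and 3 gave as many lists as the real 11 (highest other 12). For the Cdk8 knockout against RasG12V, 10 gave as many genes as the real 0 (highest other 1), which any split must, so that count decides nothing. For lists 10 gave as many as the real 2 (highest other 10). For the Cdk19 knockout, 1 gave as many genes as the real 2 (highest other 0) and 6 as many lists as the real 8 (highest other 10).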

How the results depend on the processing

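The settings without both replicates 3 (untransformed and RasG12V) and with library quality weights, and the list counts between the knockouts, were chosen after the data had been seen; the others were planned, and the cause of the changes was not tested unless the setting itself uses fewer libraries or a stricter threshold. Named genes were run with RLE, DESeq2, the unstranded column, the title block, 1 library left out, both replicates 3 left out and weights. Of their 243 values 106 passed with all libraries and 0 of these reversed under those settings, while 20 that had not passed reversed in at least 1. Leaving out 1 library kept 2706 values on their side of the threshold and made 148 weaker, 34 stronger and 28 reversed. RLE, upper quartile scaling, the CPM filter, limma-voom, the unstranded column and leaving out mitochondrial, ribosomal RNA and histone genes kept every count of genes within 1.5 times. The biological coefficient of variation was 13.9%, and 6.69% without both replicates 3; the comparisons were not fitted at a lower depth.

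For RasG12V against untransformed the count of 3340 became 5799 without both replicates 3, 6675 with quality weights, 1574 with only the 2 groups, 1010 against a fold of 1.5 and 1925 at 0.01; without 1 library it ran from 2359 to 4808. For the Cdk8 knockout the count of 0 became 16 without a filter, 30 with DESeq2, 231 without both replicates 3 and 129 with weights; without 1 library it ran from 0 to 3. For the Cdk19 knockout the count of 2 became 84 without a filter, 66 with DESeq2, 291 without both replicates 3, 280 with weights, 1 with only the 2 groups, 0 against a fold of 1.5 and 0 at 0.01; without 1 library it ran from 0 to 21. Between the knockouts the count of 15 became 108 without a filter, 106 with DESeq2, 771 without both replicates 3, 576 with weights, 496 with only the 2 groups, 1 against a fold of 1.5 and 5 at 0.01; without 1 library it ran from 0 to 133.

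Genes changed the same way in both knockouts went from 0 to 3 without a filter, 5 with DESeq2, 43 without both replicates 3 and 25 with weights; without 1 library from 0 to 1. RasG12V genes moved back in the Cdk8 knockout went from 0 to 9, 15, 149 and 72 under the same settings, and from 0 to 3 without 1 library. Those moved back in the Cdk19 knockout went from 1 to 29, 30, 146 and 141, and from 0 to 7 without 1 library. Gene lists called for RasG12V went from 11 to 0 with an estimated correlation and 17 by fry, and from 10 to 13 without 1 library. For the Cdk8 knockout they went from 2 to 4 without both replicates 3, 0 with an estimated correlation and 0 by fry, and from 2 to 6 without 1 library. For the Cdk19 knockout they went from 8 to 5 without a filter, 0 without both replicates 3, 0 with an estimated correlation and 0 by fry, and from 2 to 10 without 1 library. Between the knockouts they went from 3 to 5 without both replicates 3, 0 with an estimated correlation and 1 by fry, and from 1 to 7 without 1 library.

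The replicate numbers of the titles and descriptions were not taken to pair libraries across groups: correlations of libraries with the same number ran from -0.168 to 0.282, over 0.1 in 8 of 18 title pairs and 5 of 14 description pairs. Pairs with different title numbers ran from -0.295 to 0.222. Untransformed replicate 1 correlated best with a library of another number (0.164). RasG12V replicate 3, however, correlated at 0.164, 0.149 and 0.282 with replicate 3 of the untransformed, Cdk8 knockout and Cdk19 knockout groups. The remaining pairs of replicates 3 were at 0.115, -0.087 and 0.068, so a pairing by title number is not excluded. RasG12V replicate 3 and Cdk19 knockout replicate 3 alone carry the description number 4 and had the highest correlation of all pairs, 0.282; the labels do not say whether that number marks a batch, so a shared batch of these 2 stays open. A block by title number gave 1 gene for the Cdk8 knockout and 2 moved back in the Cdk19 knockout; a block by description number gave 12 genes for the Cdk19 knockout and 7 moved back there. By title number, 4 log2 fold changes reversed: Hras and Hmgcs1 in the Cdk8 knockout to 0.021 and 0.004, and Lgals4 and Smim6 in the Cdk19 knockout to 0.152 and 0.042. That block also lost 4 calls. They were Gm38020 in the Cdk19 knockout (adjusted p = 0.0671) and, between the knockouts, Cfap69, Pls3 and Pdlim5 (0.0654, 0.0654 and 0.0695).

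The other reversed log2 fold changes were against RasG12V. For Hras in the Cdk8 knockout they were 0.001 with RLE, 0.002 with DESeq2 and 0.011 with the unstranded column. Without both replicates 3, and with weights, Lgals4 was 1.096 and 0.949, Tapbp 0.597 and 0.528, Hmgcs1 0.309 and 0.239 and Rbp4 0.490 and 0.419 in the Cdk8 knockout. In the Cdk19 knockout the same settings gave Apoa1 0.529 and 0.443, Cdk8 -0.027 and -0.030, Foxm1 -0.030 and -0.001, Lgals4 1.581 and 1.461, Rbp4 0.207 and 0.110, Smim6 0.920 and 0.832, and Tapbp 0.654 and 0.549, and Kif11 was -0.032 without both. Without 1 library the ranges in the Cdk8 knockout were -0.210 to 0.138 for Hras, -1.039 to 1.094 for Lgals4, -0.019 to 0.867 for Scd1, -0.135 to 0.434 for Fdft1, -0.199 to 0.310 for Hmgcs1, -0.526 to 0.491 for Rbp4 and -0.665 to 0.598 for Tapbp. In the Cdk19 knockout they were -0.670 to 0.046 for Akap12, -1.946 to 0.523 for Apoa1, -0.033 to 0.045 for Cdk8, -0.036 to 0.369 for Foxm1, -0.144 to 1.485 for Gstm1, -0.309 to 0.038 for Hras, -0.065 to 0.563 for Ifitm2, -0.037 to 0.364 for Kif11, -0.556 to 1.575 for Lgals4, -0.815 to 0.202 for Rbp4, -0.133 to 0.753 for Scd1, -0.415 to 0.916 for Smim6 and -0.613 to 0.651 for Tapbp.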

Other observations

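Some lists that did not pass as a whole with RasG12V held genes that changed. Among cytokines, Csf2, which drives myeloid growth, rose by 2.79 (SE 0.35) from 0.858 ± 0.600 to 6.03 ± 1.72 CPM, and Lif rose by 1.31 (SE 0.17) from 32.9 ± 4.16 to 81.5 ± 20.7 CPM. Tslp was at 0 CPM in untransformed cells and at 0.591 ± 0.221 CPM in RasG12V. Of the CDK inhibitors, which hold the cell cycle, Cdkn2a rose by 0.60 (SE 0.18, 94.8 to 144 CPM) and Cdkn2b by 0.84 (SE 0.22), while Cdkn2c fell by 0.91 (SE 0.21). Cdkn2a did not pass without untransformed replicate 1 or 2 or RasG12V replicate 3 (adjusted p = 0.116, 0.115 and 0.0542), nor Cdkn2b without untransformed replicate 1 or 2 (0.0666 and 0.0614). The p53 target Mdm2 rose by 0.53 (SE 0.08) from 828 ± 48.4 to 1197 ± 101 CPM, and the epoxide hydrolase gene Ephx1 fell by 1.85 (SE 0.35; 2.56 without both replicates 3). In Notch signalling Nrarp rose by 1.35 (SE 0.14) and Hey1 fell by 2.61 (SE 0.27), and the interferon gene Mx1 fell by 4.54 (SE 0.80; 6.36 without both replicates 3).

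Msln, a mesothelial marker, was abundant in untransformed and RasG12V cells at 1465 ± 162 and 1344 ± 45.7 CPM (log2 fold change -0.12, SE 0.09, adjusted p = 0.333). The uroplakin genes Upk1b and Upk3b fell by 1.97 (SE 0.31) and 4.51 (SE 0.65; 3.57 for Upk3b without both replicates 3). The mucin gene Muc16 rose by 2.52 (SE 0.71; 3.51 without both replicates 3) but did not pass without untransformed replicate 2 or RasG12V replicate 1 or 2 (adjusted p = 0.0700, 0.101 and 0.0553). In untransformed replicate 3 the 5 mesothelial markers had a median log2 ratio of 0.80 against replicates 1 and 2, and 23 of 25 cholesterol and lipid synthesis genes were higher there, with a median of 0.30. In RasG12V replicate 3 again 23 of 25 were higher, with a median of 0.36.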
